A study of Mus musculus with 10 samples.

How the data were processed

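Total RNA of mouse telencephalon at embryonic day 12 was sequenced in 10 samples: 5 wild type, 2 with a null allele of Polr1a and 3 with a missense allele. The zygosity of each sample and the sequencing depth are not given in the sources used here. The deposited file lists 1 value per gene and sample, in log2 units, and its name states that the authors filtered and normalized the values. The unit was read from the values: in each sample the back-transformed values sum to nearly the same total (1000570 to 1000990), all samples share a floor of -3.16, and the largest value is 13.07, as for log2 CPM, the read counts scaled to each sample's total, with a small offset. No factor between samples beyond each sample's own total is visible. Values near the floor do not fall in whole-read steps, so no counts were recovered, and no counting interval is given. Every gene was above 0 in at least 2 samples. The genome build named by the labels is GRCm39, and aligner, counter and annotation are not given in the sources used here. The file holds 14797 genes, of which 1 has no name and was left out.

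Samples were put into 4 groups by genotype and by the first number in their titles: wild type of the null set, whose titles begin with Polr_2048 (2 samples), null (2), wild type of the missense set, whose titles begin with Polr_2138 (3), and missense (3). A linear model with these groups was fitted to the deposited log2 values of 14796 genes with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on the mean level, 6 residual degrees of freedom and 4.83 prior degrees of freedom. The contrasts were null and missense, each minus the wild type of its set, the difference and the mean of these, and wild type of the missense set minus wild type of the null set. All tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure the spread between these samples, and the labels do not say whether samples share a litter. Tables were handled in R with version 1.17.8 of the data.table package, and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

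For 30 gene lists, camera was run with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The lists cover RNA polymerase I and ribosome biogenesis, p53 and stress responses, ribosomal proteins, the cell cycle, and markers of the regions and cell types in and around the telencephalon. The model, the contrasts, the lists and the rule for named genes were fixed before the data were examined. The rule takes Polr1a, then for each mutant up to 10 called genes in each direction with the largest log2 change, at or above the 25th percentile of the mean level and not predicted gene models or pseudogenes, or, where fewer than 5 pass, those of smallest p up to 5. For each described list it takes up to 3 members with the smallest p, and for the difference up to 5 genes in each direction. The values of some genes that meet the rule are not reported here. Polr1a was also tested with an exact 2-sided permutation test.

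On simulated data with the residual spread of each gene, the null contrast recovered 4.48%, 40.3% and 81.8% of genes given log2 changes of 0.5, 1 and 2, with 4 false calls, and the missense contrast recovered 19.4%, 56.7% and 83.3%, with 8 false calls. A shift of 0.3 in the p53 list was recovered in both. Genes were simulated independently of each other, so this does not show how camera performs where genes are correlated. Alternatives were no title-number term, median-centred or quantile-normalized samples, a filter at the 25th percentile of the level, no trend, robust variances, sample weights, the samples of 1 title number alone and leaving out each sample in turn. Where a fit left 1 sample in a group, that sample was taken to vary like the other groups. For 60 splits that reassign samples within their title number, and 10 splits of the samples of the missense set, the fits were repeated. Gene order was taken from reference annotation of another genome build, in which 13853 symbols matched directly and 98.5% of genes matched in all, so no coordinates are given. Levels of 4 Y-linked genes showed both sexes in the wild types of each title number and in each mutant group, and Xist has no value in the file. Correlations between samples ran from 0.938 to 0.964, with no duplicate.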

Results

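Gene expression was measured by RNA sequencing of total RNA from the telencephalon, the embryonic forebrain region that forms the cerebral cortex and basal ganglia, of mouse embryos at day 12 of gestation. The 10 samples carried a null allele of Polr1a (2 samples), a missense allele of Polr1a (3 samples) or no mutant allele (5 wild-type samples). Polr1a encodes the largest subunit of RNA polymerase I, the enzyme that transcribes ribosomal RNA genes, and the missense allele changes the protein at C1559F. Both null samples and wild types 1 and 2 have titles that begin with Polr_2048, here called the null set, and the missense samples and wild types 3, 4 and 5 have titles that begin with Polr_2138, here called the missense set. The labels do not say what these title numbers mean, and each mutant was compared with the wild types of its own set. The deposited table holds log2 values for 14797 genes, of which the 14796 with a name were tested. The sequencing depth of each sample is unknown, because the back-transformed values of each sample sum to nearly the same total, between 1000570 and 1000990, whatever its depth was.

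Polr1a itself was measured to check the alleles against the RNA level. Its mean log2 level was 4.91 ± 0.12 (SD, n = 2) in the null samples and 5.38 ± 0.00396 (SD, n = 2) in the wild types of the null set, a difference of -0.48 (SE 0.20, limma adjusted p = 0.563). Both null samples, at 4.99 and 4.82, lay below both wild types of the null set, each at 5.38. An exact 2-sided permutation test gave p = 0.333, the smallest value that 2 samples against 2 allow. In the missense samples the mean was 5.51 ± 0.37 (SD, n = 3) against 5.59 ± 0.07 (SD, n = 3) in the wild types of the missense set, a difference of -0.08 (SE 0.16, limma adjusted p = 0.964). The exact 2-sided permutation p of the missense comparison was 1, where 0.1 is the smallest that 3 against 3 can reach. Missense 1, at 5.09, decided the sign of the missense difference, which was 0.13 without it. Polr1a lies on chromosome 6.

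The null comparison asked which genes differ in the telencephalon with a null allele of Polr1a. Genes of the ventral telencephalon fell in the null samples. Dlx1, a homeobox gene of GABAergic progenitors, fell by 1.38 on the log2 scale (SE 0.10, n = 2 against 2, adjusted p = 0.000369), and its paralogue Dlx2 fell by 1.68 (SE 0.20, adjusted p = 0.0128). Lhx6 fell by 2.50 (SE 0.30, adjusted p = 0.0128), Lhx8 by a log2 change of -3.58 (SE 0.58, adjusted p = 0.0464) and Nkx2-1, which specifies the medial ganglionic eminence, by -1.91 (SE 0.30, adjusted p = 0.0443). Gad2, an enzyme of GABA synthesis, fell by 1.35 (SE 0.15, adjusted p = 0.00996). Wnt8b, a gene of the cortical hem at the dorsal midline, rose by 1.08 (SE 0.14, adjusted p = 0.0220).

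In limma, 24 of 14796 genes passed an adjusted p of 0.05 in the null comparison, 5 higher and 19 lower, and 1231 genes had an unadjusted p under 0.05 where 739.8 are expected by chance. Among the genes that fell were also Arl4d (log2 change -2.24, SE 0.23, adjusted p = 0.00951), Gbx1 (-2.48) and Sox8 (-2.25). The genes that rose included Tmem132c (0.80, SE 0.10, adjusted p = 0.0198), Nr6a1 (2.16, SE 0.35, adjusted p = 0.0491) and Rpl15 (0.74, SE 0.11, adjusted p = 0.0277). Rpl15 also differed between the wild types of the 2 title numbers, by 0.75. It missed the threshold without the title-number term (0.29, adjusted p = 0.706). Rspo3, a Wnt agonist, had a log2 change of 0.83 (SE 0.14) and missed the threshold (adjusted p = 0.0597). It passed without missense 1 (adjusted p = 0.0478) and without missense 3 (0.0368). Dlx1 passed in all 10 fits that each left out 1 sample, and Arl4d in 9 of them (adjusted p = 0.0756 without null 2). Gad2, Dlx2 and Lhx6 passed in 8, with adjusted p of 0.0691, 0.0754 and 0.0718 without wild type 2 and of 0.10, 0.126 and 0.126 without null 2. Wnt8b passed in 6, with adjusted p of 0.0953 without wild type 1, 0.0551 without null 1, 0.0718 without wild type 2 and 0.175 without null 2. Tmem132c passed in 6, missing without null 1, wild type 2, null 2 and wild type 3 (adjusted p of 0.0648, 0.0908, 0.167 and 0.0552), and Rpl15 passed in 4, with adjusted p of up to 0.227 without null 2. Lhx8, Gbx1, Sox8 and Nkx2-1 each passed in 1 of the 10 limma fits, with adjusted p of up to 0.167, 0.164, 0.179 and 0.174, and Nr6a1 in 0, with adjusted p of 0.0594 to 0.234. The count was 12 without wild type 1, 7 without wild type 2, 2 without null 2, 8 without wild type 3, 12 without wild type 5, 14 without missense 2, and 12 without wild type 4 and missense 3 together. It was 59 without a term for the title number, 6 without the trend of the variance on the level and 0 with the 4 samples of the null set alone, where 1101 genes had an unadjusted p under 0.05 in limma.

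**Figure D1:**
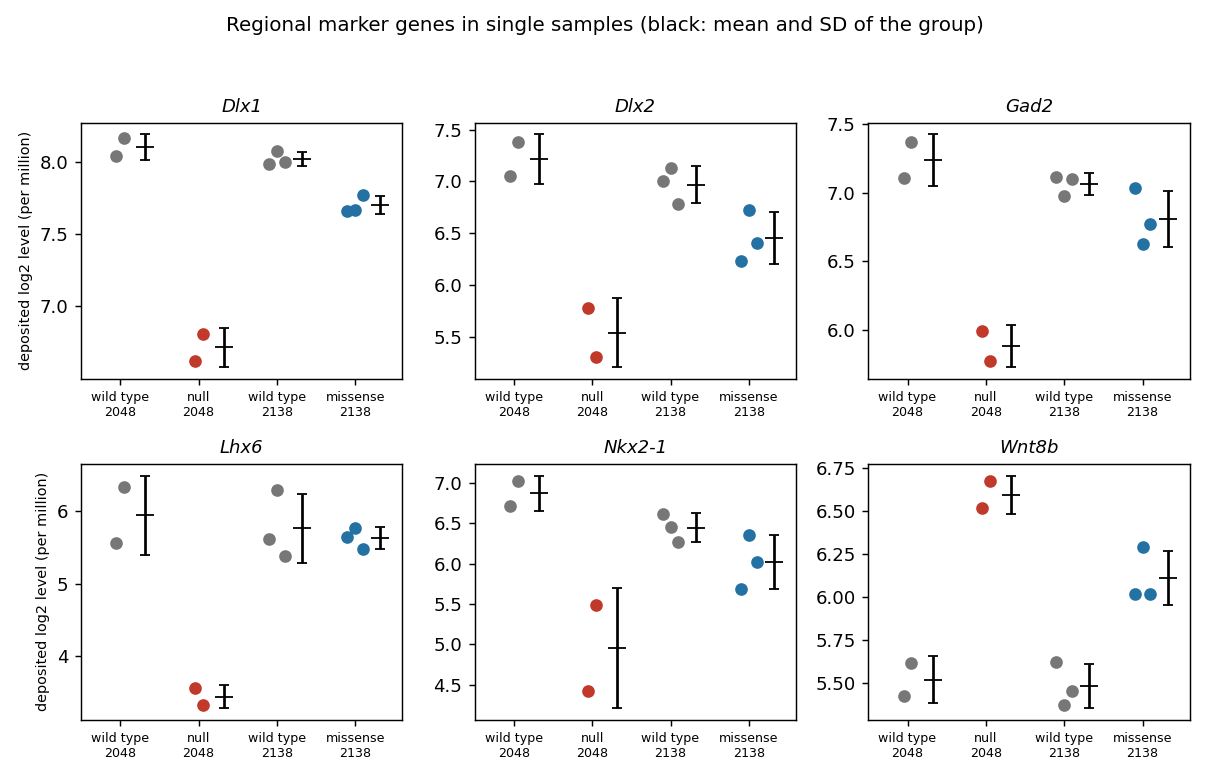
Deposited log2 level of 6 regional marker genes in each sample, by group and title number, with the mean and SD of each group in black. Dlx1 lay at 6.62 and 6.81 in the null samples, below 8.04 and 8.16 in the wild types of the null set, and Wnt8b lay at 6.51 and 6.67 in the null samples, above 5.42 and 5.61.

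Gene lists fixed before the data were examined described these regions further. The list of the ventral telencephalon and GABAergic lineage fell in the null samples, with a median log2 change of -0.80 over 34 measured genes (median fold 0.573), of which 26 were lower and 8 higher (camera adjusted p = 5.12e-15). In this list 10 genes fell and 0 rose over all genes tested, and 20 fell and 2 rose, Foxp2 (0.70) and Maf (0.50), when adjusted over the list alone, the latter pair named after their values were seen. The list of the cortical hem and Cajal-Retzius cells rose, with a median of 0.65 over 29 genes, 27 of them higher (adjusted p = 4.36e-13). Over all genes 1 of its members rose and 0 fell, and 18 rose when adjusted over the list alone, among them Wnt8b and Bmp6 (log2 change 1.46, limma adjusted p = 0.128 over all genes). Both calls held with an estimated correlation between genes (adjusted p = 0.00226 for each). Choroid plexus genes rose, with a median of 0.62 and 16 of 17 higher (adjusted p = 5.63e-07; adjusted p = 0.0521 with an estimated correlation), and 0 passed in limma over all genes or adjusted over the list alone, with 7 higher at an unadjusted p under 0.05. Without the title-number term the choroid plexus call was lost (median 0.28, adjusted p = 0.0849). Targets of the Wnt pathway rose by a median of 0.38, with 15 of 20 higher (adjusted p = 0.000212; adjusted p = 0.111 with an estimated correlation). Adjusted over the list alone, 7 of these rose, with Apcdd1 at 0.69, Axin2 at 0.63 and Tnfrsf19 at 0.53, against 0 over all genes in limma, where 8 had an unadjusted p under 0.05.

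Markers of brain regions outside the telencephalon rose in the null samples, as hem genes did, while ventral genes fell. The list of the diencephalon, hypothalamus, eye and midbrain rose by a median of 0.93, with 29 of 38 genes higher (camera adjusted p = 9.79e-05; adjusted p = 0.492 with an estimated correlation). Over all genes 0 of its members passed in limma, with 16 higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 11 rose and 1 fell. Irx2 had a log2 change of 1.5 (SE 0.27, limma adjusted p = 0.0757), Irx5 of 1.39, and Vax1, which the ventral forebrain also expresses, of -2.36 (SE 0.42, limma adjusted p = 0.0700). Without null 2 the median of this list was 0.63 and the call was lost (adjusted p = 0.155).

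Markers of non-neural cells were higher in the same null samples. Microglia and macrophage genes rose by a median of 1.01 (2.01-fold), with all 24 measured genes higher (camera adjusted p = 1.73e-17; adjusted p = 0.0318 with an estimated correlation). Adjusted over the list alone 14 rose, with Csf1r at 0.95 (SE 0.17), Mrc1 at 1.04 (SE 0.20) and Cx3cr1 at 0.98 (SE 0.19), while over all genes 0 passed in limma and 15 had an unadjusted p under 0.05. Mesenchyme, neural crest and meninges genes rose by a median of 0.59, with 40 of 42 higher (adjusted p = 2.10e-08; adjusted p = 0.492 with an estimated correlation), among them Osr1 at 1.09. Surface and olfactory epithelium genes rose by a median of 0.68, with 24 of 26 higher (adjusted p = 0.000498; adjusted p = 0.492 with an estimated correlation). Endothelium and pericyte genes rose by a median of 0.28, with 31 of 34 higher (adjusted p = 9.79e-05; adjusted p = 0.492 with an estimated correlation), and erythroid genes by 0.27, with 20 of 26 higher (adjusted p = 0.00639; adjusted p = 0.496 with an estimated correlation). Without null 2 the endothelial call was lost (median 0.10, adjusted p = 0.186), and the erythroid call was lost without null 2 (adjusted p = 0.301) and without wild type 2 (median 0.06, adjusted p = 0.653). In each of the mesenchymal, epithelial, endothelial and erythroid lists 0 genes passed in limma over all genes or adjusted over the list alone, while 16, 7, 5 and 5 genes, all higher, had an unadjusted p under 0.05.

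Neuronal genes were lower in the null samples. The pan-neuronal list fell, with a median of -0.22 and 25 of 32 genes lower (camera adjusted p = 2.38e-05; adjusted p = 0.492 with an estimated correlation), with Stmn4 at -0.60. Adjusted over the list alone Elavl3 fell (-0.37) and Thsd7a rose (0.88), and the list missed the threshold without null 1 (median -0.11, adjusted p = 0.167). Intermediate progenitor and newborn cortical neuron genes had a median of -0.13, with 16 of 26 lower (adjusted p = 0.0409, or 0.492 with an estimated correlation). That list missed the threshold of camera with the Y-linked level as a covariate (adjusted p = 0.0532) and without wild type 4 and missense 3 together (0.0961). Bcl11b, a transcription factor of cortical and striatal neurons, had a log2 change of -0.91 (SE 0.16, limma adjusted p = 0.0566) and was the 1 gene of that list to fall when adjusted over the list alone. The call of that list was lost without wild type 2 (adjusted p = 0.390), null 2 (0.183), wild type 3 (0.0522) or missense 3 (0.0772), and with quantile normalization (0.0888). Genes encoded in mitochondrial DNA rose by a median of 0.24, with 10 of 13 higher (adjusted p = 0.0185; adjusted p = 0.503 with an estimated correlation), with mt-Co3 (0.82) past the threshold adjusted over the list alone, and the call was lost without wild type 2 (0.0841) and null 2 (0.146). Mitochondrial ribosomal protein genes had a median of -0.05, with 46 of 75 lower (adjusted p = 0.0415; adjusted p = 0.678 with an estimated correlation). Their median was 0.11 without wild type 1 (adjusted p = 0.33) and 0.03 without the title-number term (0.762), and the call was also lost without null 1 (0.329), wild type 3 (0.0522), wild type 4 (0.0519), wild type 5 (0.0509) or missense 3 (0.0518).

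Targets of p53, the transcription factor activated by DNA damage and by nucleolar stress, rose in the null samples. The median log2 change was 0.22, with 32 of 43 measured genes higher (camera adjusted p = 0.000169; adjusted p = 0.0292 with an estimated correlation). Adjusted over the list alone 5 genes rose, Ccng1 (0.92, SE 0.16), Eda2r (2.17, SE 0.42), Cdkn1a (1.02, SE 0.27), Sesn2 (0.94) and Sulf2 (0.66, SE 0.16), while over all genes 0 passed in limma, the nearest being Ccng1 (adjusted p = 0.0688), and 11 were higher at an unadjusted p under 0.05. Cdkn1a and Sesn2 were named in null after their values were seen.

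The missense comparison asked which genes differ in the telencephalon with the missense allele. Eda2r, a p53 target that encodes a receptor of the tumour necrosis factor family, rose by 2.63 on the log2 scale (SE 0.34, n = 3 against 3, adjusted p = 0.0499). The limma call of Eda2r was lost with the Y-linked level as a covariate (adjusted p = 0.137) and without wild type 4 and missense 3 together (0.173). It was also lost without predicted gene models, pseudogenes and ribosomal protein genes (0.0888). The mean level of Eda2r lay below the 25th percentile of the genes tested, so the filter at that level left it out. Rpl34, a gene of the large ribosomal subunit, fell by 3.76 (SE 0.19, adjusted p = 9.48e-06), from a mean of 7.72 ± 0.13 (SD, n = 3) in wild type to 3.96 ± 0.38 (SD, n = 3). The summed level of Rpl34 and its pseudogene Rpl34-ps1, which was chosen after its values were seen, differed by -0.97, and on the linear scale of the deposited values the mean of the pseudogene rose by 65.2 while that of Rpl34 fell by 195. Gm3608, a predicted gene model named here after its values were seen, rose by 3.61 (SE 0.27, adjusted p = 0.000343). It also differed between the wild types of the missense and null sets, by -4.07, and missed the threshold without the title-number term (adjusted p = 0.716). These 3 genes, 2 higher and 1 lower, were the ones that passed in limma, while 819 genes had an unadjusted p under 0.05 against 739.8 expected by chance.

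Further genes of the missense comparison had small unadjusted p without passing. Ccng1, a cyclin gene induced by p53, had a log2 change of 0.97 (SE 0.13, adjusted p = 0.0608) and Cdkn1a, an inhibitor of the cell cycle, of 1.0 (SE 0.22, adjusted p = 0.884). Wnt8b had 0.63 (SE 0.12, adjusted p = 0.546), Dhx30 2.50 (SE 0.47) and the microglial gene Fcrls 0.95 (SE 0.21). Lower values were those of Rlbp1 (-0.99, SE 0.19), Tbc1d17 (-0.57), Podxl2 (-0.38) and Ccdc141 (-1.62), with adjusted p between 0.546 and 0.884. Rpl34 and Gm3608 passed in all 10 fits that left out 1 sample. Eda2r missed without wild type 1 (adjusted p = 0.109), wild type 2 (0.105), wild type 3 (0.0762), wild type 5 (0.0659), missense 1 (0.263), missense 2 (0.191) and missense 3 (0.346), as well as after median centring (0.0562), quantile normalization (0.0747) or without the trend (0.253), and Ccng1 passed without null 1 (0.0470), null 2 (0.0432) or wild type 4 (0.00919). The limma count was 6 without null 1, 6 without null 2, 10 without wild type 4, 8 without wild type 4 and missense 3 together, and 0 without predicted gene models, pseudogenes and ribosomal protein genes, where 748 genes had an unadjusted p under 0.05.

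**Figure D2:**
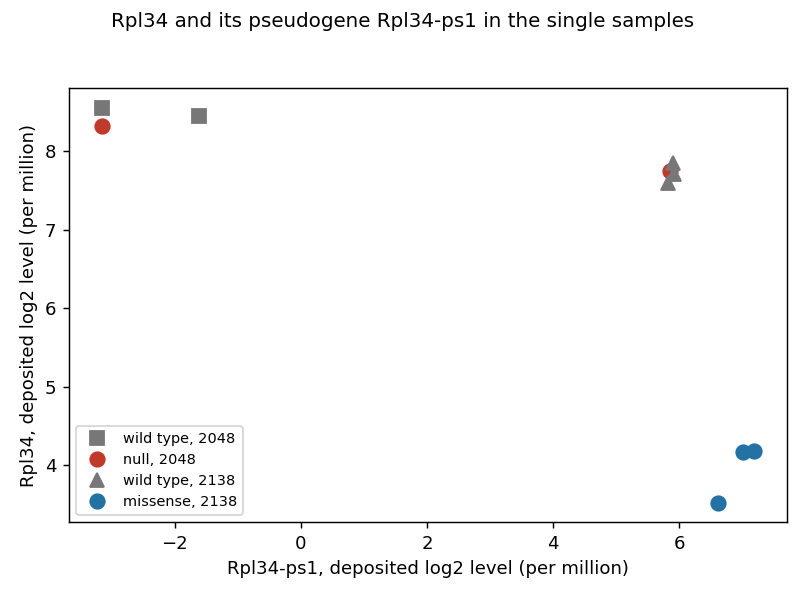
Deposited log2 level of Rpl34 against that of its pseudogene Rpl34-ps1, 1 point per sample, with shapes and colours for the groups. The 3 missense samples lay at 3.53 to 4.19 for Rpl34 and 6.62 to 7.19 for Rpl34-ps1, and the wild types of the missense set at 7.60 to 7.86 and 5.83 to 5.91.

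Among the gene lists, p53 targets rose in the missense samples. Their median log2 change was 0.26 (1.20-fold), with 35 of 43 genes higher (camera adjusted p = 1.05e-07; adjusted p = 0.0143 with an estimated correlation). Over all genes 1 member rose, Eda2r, and 7 rose when adjusted over the list alone, among them Ccng1 and Cdkn1a. Microglia and macrophage genes rose by a median of 0.49 in the same samples, with 21 of 24 higher (adjusted p = 4.93e-08; adjusted p = 0.122 with an estimated correlation). Cx3cr1 had a log2 change of 0.53 (SE 0.16) and C1qb of 0.77 (SE 0.23), and 0 genes of the list passed in limma over all genes or adjusted over the list alone, with 8 higher at an unadjusted p under 0.05.

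Cytosolic ribosomal protein genes fell in the missense samples, with a median log2 change of -0.14 and 67 of 78 genes lower (camera adjusted p = 1.05e-07; adjusted p = 0.635 with an estimated correlation). Of these 1 gene, Rpl34, fell over all genes and also adjusted over the list alone, Rpl10a had a log2 change of -0.31 and Rps13 of 0.85. Intermediate progenitor and newborn cortical neuron genes fell, with a median of -0.22 and 23 of 26 lower (adjusted p = 1.05e-07; adjusted p = 0.122 with an estimated correlation), with Neurod2 at -0.64, Bcl11b at -0.44 and Insm1 at -0.41. The pan-neuronal list had a median of -0.12, with 27 of 32 lower (adjusted p = 0.000393; adjusted p = 0.543 with an estimated correlation), and was lost without missense 3 (median -0.06, adjusted p = 0.10) and without the title-number term (median 0.01, adjusted p = 0.315). In both neuronal lists 0 genes passed in limma over all genes or adjusted over the list alone, with 9 and 2 lower at an unadjusted p under 0.05.

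The ventral telencephalon, hem, Wnt target and choroid plexus lists moved in the missense samples in the direction seen in the null samples. The median of dorsal pallium markers, a list chosen after the results were seen, differed in sign, at -0.16 in missense and 0.10 in null. Their means did not, at -0.20 in missense and -0.08 in null. The ventral telencephalon list fell, with a median of -0.22 and 25 of 34 lower (camera adjusted p = 0.00116; adjusted p = 0.105 with an estimated correlation), and Dlx1 (-0.32, SE 0.08) and Sp9 (-0.48, SE 0.13) fell when adjusted over the list alone, a count of 2 against 0 over all genes in limma, where 7 were lower at an unadjusted p under 0.05. The hem list rose by a median of 0.20, with 23 of 29 higher (adjusted p = 0.000881; adjusted p = 0.0925 with an estimated correlation), and 2 genes, Wnt8b and Rspo2 (1.94, SE 0.49), rose when adjusted over the list alone, against 0 over all genes in limma, where 6 were higher at an unadjusted p under 0.05. Wnt pathway targets rose by a median of 0.15, with 17 of 20 higher (adjusted p = 0.000444; adjusted p = 0.122 with an estimated correlation), with 1 gene, Rnf43 (2.62, SE 0.43), past the threshold adjusted over the list alone. Choroid plexus genes rose by a median of 0.19, with 13 of 17 higher (adjusted p = 0.0492; adjusted p = 0.524 with an estimated correlation). That call was lost without null 1 or null 2 (adjusted p = 0.0511 each), wild type 3 (0.177), missense 1 (0.133), wild type 5 (0.0801) or missense 3 (0.311).

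Surface and olfactory epithelium genes rose in the missense samples by a median of 0.53, with 24 of 26 higher (camera adjusted p = 0.000307; adjusted p = 0.543 with an estimated correlation). Mesenchyme, neural crest and meninges genes rose by a median of 0.31, with 38 of 42 higher (adjusted p = 0.000828; adjusted p = 0.735 with an estimated correlation). Missense 3 decided both, since without it the medians were 0.09 and 0.12 (adjusted p = 0.388 for each). The mesenchyme call was also lost without wild type 4 (median 0.07, adjusted p = 0.833), and without both samples the median was -0.13 (adjusted p = 0.00887). In both lists 0 genes passed in limma over all genes or adjusted over the list alone, with 2 in each higher at an unadjusted p under 0.05.

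**Figure D3:**
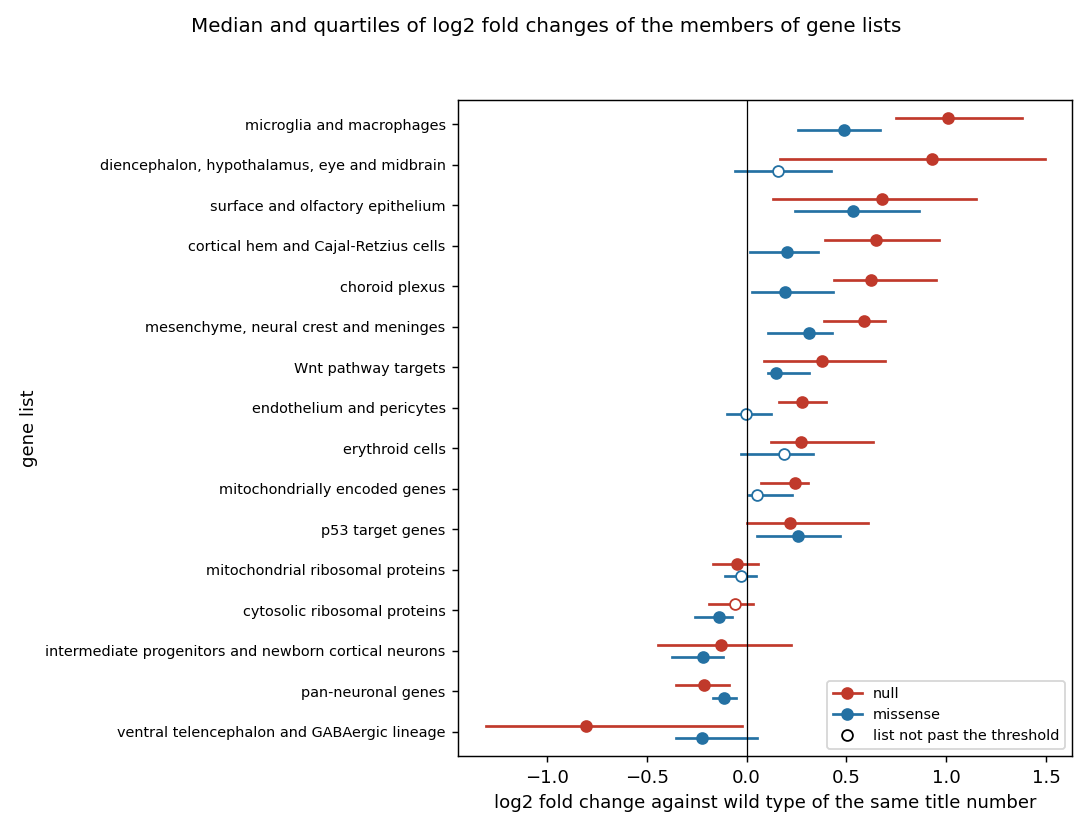
Median (circle) and quartiles (line) of the log2 fold changes of the genes of each list that passed in at least 1 mutant, for null (red) and missense (blue) against the wild types of the same title number; open circles mark lists that did not pass the threshold of camera. Of the lists drawn, the ventral telencephalon lay lowest, at -0.80 in null and -0.22 in missense, and microglia highest in null, at 1.01.

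Lists of the machinery that Polr1a belongs to did not pass in either mutant against the wild types of its own set. Genes of RNA polymerase I subunits had a median log2 change of -0.02 in null (camera adjusted p = 0.680) and -0.08 in missense (0.113), and ribosome biogenesis factors of 0.05 in both (0.901 and 0.343). Cofactors of RNA polymerase I (0.354 and 0.965), targets of the integrated stress response (0.444 and 0.942), genes of S phase (0.351 and 0.826), genes of G2 and M phase (0.0997 and 0.878), radial glia genes (0.167 and 0.226) and apoptosis effectors (0.252 and 0.234) did not pass in null or missense, respectively. The same held for hypoxia and glycolysis (0.351 and 0.670), cholesterol synthesis (0.603 and 0.0663), immediate early and heat shock genes (0.439 and 0.826), the Sonic hedgehog pathway (0.680 and 0.826), genes of X inactivation and the Y chromosome (0.905 and 0.312) and the 2 measured snoRNA host genes (0.327 and 0.687). Cytosolic ribosomal proteins did not pass in null (median -0.06, adjusted p = 0.166), nor did the diencephalon list (median 0.16, adjusted p = 0.312), endothelial genes (0.856), erythroid genes (0.0848), mitochondrially encoded genes (0.826) and mitochondrial ribosomal proteins (0.0656) in missense. Leaving out 1 sample changed several of these results. In null the cytosolic ribosomal list passed as higher without wild type 1 (median 0.19) and as lower without wild type 2 (-0.31) or null 2 (-0.15). Genes of G2 and M phase passed as lower without null 1 (median -0.12, adjusted p = 0.000702) or wild type 1 (0.0223), genes of S phase without null 1 (0.0395), and snoRNA host genes as higher without wild type 1 (median 1.16, adjusted p = 0.0311). In missense the diencephalon list passed without wild type 3 (median 0.38, adjusted p = 0.0235), as did cholesterol synthesis (0.0404). Erythroid genes passed without wild type 4 (0.000263) or missense 3 (0.0221), mitochondrially encoded genes without wild type 4 (0.0194), and the X and Y genes in 1 of 10 fits (0.0342). Mitochondrial ribosomal proteins passed as lower in 5 of 10, with adjusted p of 0.0177 to 0.0455. Without the title-number term 16 lists passed in missense, 10 of them among the 11 called with it. The other 6, all lower, were RNA polymerase I subunits (adjusted p = 0.0497), S phase (0.0250), G2 and M phase (0.00264), radial glia (0.0116), cholesterol synthesis (0.000810) and mitochondrial ribosomal proteins (8.73e-05). After median centring cholesterol synthesis and mitochondrial ribosomal proteins passed in missense (0.0460 each) and genes of G2 and M phase in null (0.0424). In null the median and the test differed in sign for cholesterol synthesis, the Sonic hedgehog pathway and the X and Y genes, and in missense for the cofactors and the genes of G2 and M phase. With an estimated correlation, 4 of the 15 lists called in null and 1 of the 11 called in missense passed.

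Both mutants were averaged to test the mean of their changes, which a change in 1 mutant alone can carry. Targets of p53 rose in the mean of both mutants. Eda2r rose by 2.40 (SE 0.27, adjusted p = 0.00529), Ccng1 by 0.95 (SE 0.10, adjusted p = 0.00529), Cdkn1a by 1.01 (SE 0.18, adjusted p = 0.0488) and Sesn2, a gene of the response to oxidative stress, by 0.88 (SE 0.15, adjusted p = 0.0488). In each of these 4 genes all 5 mutant samples lay above every wild type of their own title number. In limma Cdkn1a missed the threshold without the trend (adjusted p = 0.149), with sample weights (0.0599) and without wild type 4 and missense 3 together (0.186). Sesn2 missed it without the trend (0.118), with sample weights (0.0522) and without these 2 samples (0.104). It also missed with quantile normalization (0.0705) and with the Y-linked level as a covariate (0.0653). The p53 list had a median of 0.26, with 34 of 43 genes higher (camera adjusted p = 1.46e-07; adjusted p = 0.00560 with an estimated correlation), and 4 of its genes rose over all genes and 9 adjusted over the list alone. Microglial genes rose beside them, with C1qb at 1.07 (SE 0.18, adjusted p = 0.0488), Cx3cr1 at 0.75 (SE 0.12, adjusted p = 0.0464) and the list at a median of 0.73, with all 24 genes higher (adjusted p = 1.21e-17; adjusted p = 0.0311 with an estimated correlation).

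The lists of the hem and of the ventral telencephalon also passed in the mean of both mutants, with medians of 0.37 (camera adjusted p = 2.56e-11; adjusted p = 0.00336 with an estimated correlation) and -0.43 (adjusted p = 4.47e-13; adjusted p = 0.00336 with an estimated correlation), and in all 10 fits that left out 1 sample. Of the hem list Wnt8b rose by 0.85 (SE 0.09, adjusted p = 0.00529) and Rspo3 by 0.56. Of the ventral list Dlx1 fell by 0.85 (SE 0.06, adjusted p = 0.000302), Dlx2 by 1.10 (SE 0.13), and Gad2 had -0.80 (SE 0.10), Lhx6 -1.32 and Nkx2-1 -1.17. Genes in neither list were Tmem132c (0.54), Sepp1 (0.54), Arl4d (-1.44), Sox8 (-1.41) and Rlbp1 (-0.91), and all of these genes passed the threshold. Several of these means were carried mostly by null. In missense alone the values were -0.13 for Lhx6, -0.25 for Gad2, -0.43 for Nkx2-1, -0.52 for Dlx2, -0.57 for Sox8 and -0.65 for Arl4d. They were 0.28 for Tmem132c and Sepp1 and 0.30 for Rspo3, and 0 of these 9 genes passed in missense, where 819 had an unadjusted p under 0.05 in limma. Rpl34, at -2.11 (adjusted p = 0.000302), passed as well, and it changed by -0.47 in null (adjusted p = 0.651). In limma 40 genes passed, 12 higher and 28 lower, against 1588 with an unadjusted p under 0.05. With the samples centred on their median 37 passed, 7 higher and 30 lower. Eda2r, Ccng1, Wnt8b, Dlx1, Dlx2, Gad2, Arl4d and Rpl34 passed in all 10 fits that left out 1 sample, while Cdkn1a and Sesn2 passed in 1 (adjusted p of up to 0.137 and 0.149) and missed after median centring (0.0506 and 0.0585). C1qb and Cx3cr1 passed in 0, with limma adjusted p of 0.0588 to 0.204 and 0.0605 to 0.186. Tmem132c passed in 8, missing without null 2 (adjusted p = 0.0688) and wild type 3 (0.0501). Lhx6 passed in 3, those without wild types 1, 4 or 5 alone, with adjusted p of up to 0.119. Rspo3, Sox8, Nkx2-1 and Rlbp1 passed in 1 each, with adjusted p of up to 0.130, 0.104, 0.111 and 0.151, and Sepp1 in 0, with limma adjusted p of 0.0632 to 0.228. The count was 20 without wild type 2, 16 without null 2, 10 without wild type 3, 15 without missense 1, 19 without wild type 5, 16 without missense 2, 18 without missense 3, 19 without wild type 4 and missense 3 together, and 13 without the trend.

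**Figure D4:**
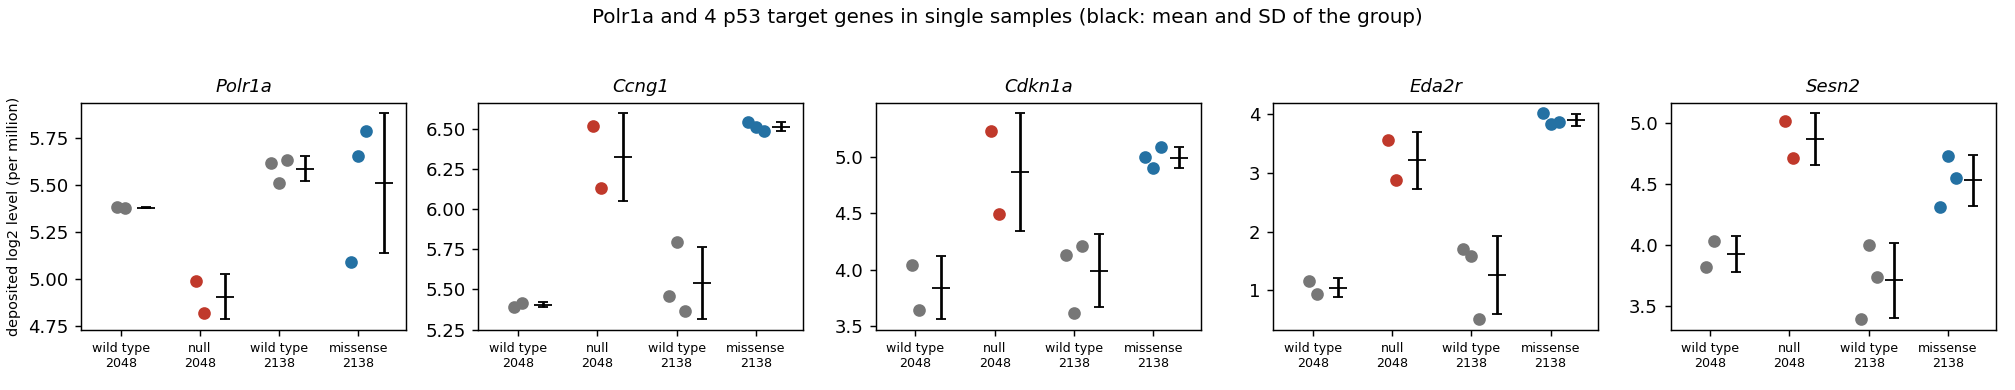
Deposited log2 level of Polr1a and 4 p53 target genes in each sample, by group and title number, with the mean and SD of each group in black. Ccng1 lay between 6.13 and 6.54 in the 5 mutant samples and between 5.36 and 5.79 in the 5 wild types.

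The test of the difference between the mutants asked which genes respond unequally to the alleles. Dlx1 fell further in null than in missense, by a difference of -1.06 (SE 0.13, adjusted p = 0.0322). Rpl34 differed by 3.29 (SE 0.30, adjusted p = 0.00425), being lower in missense. These 2 genes passed in limma, 1 in each direction, and 611 genes had an unadjusted p under 0.05, fewer than the 739.8 expected by chance. Lhx6 (-2.37, SE 0.38, adjusted p = 0.225), Gad2 (-1.10, SE 0.19, adjusted p = 0.287), Arl4d (-1.59), Gbx1 (-2.35), Rpl15 (0.86, adjusted p = 0.225), Nr6a1 (2.18), Stard8 (1.18) and Tbc1d17 (0.98) did not pass. Among the lists, the ventral telencephalon fell further in null (median difference -0.49, camera adjusted p = 5.49e-10; adjusted p = 0.0124 with an estimated correlation) and the hem rose further (0.40, adjusted p = 7.06e-07; adjusted p = 0.0124 with an estimated correlation). The p53 list did not differ past the threshold (median difference 0.02, adjusted p = 0.749), although its test pointed down. Rpl34 passed in all 10 fits that left out 1 sample, and Dlx1 passed without wild type 1 or wild type 4 but missed in the other 8, with adjusted p from 0.0626 without null 2 to 0.184 without wild type 3. The limma count was 4 without wild type 1, 6 without null 1, 4 without wild type 2, 10 without wild type 4, 1 without each other sample, 11 without wild type 4 and missense 3 together, 9 without the title-number term and 0 without the trend, where 646 genes had an unadjusted p under 0.05.

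Genes called in null were followed in missense, whose samples share no controls with them. Of the 24 genes, 21 had the same sign in missense, 18 of the 19 lower genes and 3 of the 5 higher ones. The lower genes had a median log2 change of -1.41 in null and -0.30 in missense. No gene was called in both by limma (0 genes, where 0.00487 are expected for independent calls), and 1231 and 819 genes had an unadjusted p under 0.05. Across all genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.104 and a Spearman rho of 0.212, and r was 0.387 among genes at or above the median level. Without the title-number term, where both mutants share controls, r was 0.301, and data simulated with no effect gave 0.33 on average over 50 simulations.

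The wild types of the missense set were compared with those of the null set to measure how far the 2 title numbers differ with no mutant allele. Some ribosomal protein genes and copies of them were among the genes that differed, while the list of cytosolic ribosomal proteins did not pass (median -0.03, camera adjusted p = 0.318). Rpsa-ps10, a pseudogene, was lower in the missense set by a log2 change of -10.51 and Rps3a2 by -9.64, while Rps3a1 rose by 0.96 (SE 0.11, adjusted p = 0.00582) and Rpsa by 0.89 (SE 0.12, adjusted p = 0.0151). Phgdh, an enzyme of serine synthesis, was lower (-0.79, SE 0.09, adjusted p = 0.00748) and Hdac5 higher (0.63). These 6 are among 14 genes that passed in limma, 7 in each direction and 7 of them predicted gene models or pseudogenes, with 1090 at an unadjusted p under 0.05. The 6 were named after their values were seen. Rpsa missed the threshold without wild types 1 (adjusted p = 0.143), 2 (0.0574) or 3 (0.0799), Phgdh without wild types 1 (0.0626) or 3 (0.0574), and Hdac5 in 9 of 10 fits that left out 1 sample (up to 0.269 without wild type 1).

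Gene lists also differed between the wild types. Choroid plexus genes were higher in the missense set by a median of 0.72, with all 17 higher (camera adjusted p = 2.66e-08; adjusted p = 0.124 with an estimated correlation), and pan-neuronal genes by 0.25, with 30 of 32 higher (adjusted p = 1.05e-07; adjusted p = 0.285 with an estimated correlation). Microglial genes were higher by a median of 0.38 (adjusted p = 2.79e-05; adjusted p = 0.276 with an estimated correlation). Genes of S phase had a median of -0.16, with all 42 lower (adjusted p = 2.28e-08; adjusted p = 0.124 with an estimated correlation), and genes of G2 and M phase of -0.16 (adjusted p = 7.94e-09; adjusted p = 0.157 with an estimated correlation). Of the 30 lists 12 passed camera, against 15 in null and 11 in missense. With an estimated correlation 0 passed, against 4 in null and 1 in missense. At the preset correlation lists thus passed in like number with no mutant allele, so such a call alone does not mark an effect of an allele. The limma count of genes was 7 without wild type 3, 9 without wild type 5, 6 without wild type 4 and missense 3 together, 8 among genes at or above the 25th percentile of the level and 3 without predicted models, pseudogenes and ribosomal protein genes.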

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

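The tests of dorsal pallium markers, of markers from outside the telencephalon, of the summed level and the gains and losses of Rpl34 and its pseudogene, and of immediate early genes were chosen only after the results were seen. The tests of the rescaled ventral list, of the chromosome region and of the Y-linked and microglial covariates were added after the planned fits had been seen and written before their own values were, and the splits were planned. That a bound had to be passed by more than its spread was applied to the tests of the chromosome region, the Y-linked level and the microglial level after their values were seen.

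The change of ventral and dorsal genes differed between the mutants, with a median over genes of null minus missense of -0.49 in the ventral telencephalon list (adjusted p = 5.49e-10; adjusted p = 0.0124 with an estimated correlation) and 0.40 in the hem list (adjusted p = 7.06e-07; adjusted p = 0.0124 with an estimated correlation), and by -1.06 in Dlx1. Scaling is argued against, because the ventral list stayed called after median centring and after quantile normalization, with a median of -0.80 in the one nearer 0. A lower share of ventral tissue with all other tissue enriched alike would raise hem and dorsal pallium markers alike. Hem markers rose above dorsal pallium markers in null by 0.546 in the median (bootstrap SE 0.194). Only genes were resampled, so that SE does not measure the spread between samples or dissections, and this explanation is not excluded. More tissue from outside the telencephalon in the null samples stays open. Markers of the diencephalon, hypothalamus, eye and midbrain had a median of 0.928 (bootstrap SE 0.273, also over genes). An effect of the null allele on ventral patterning may also contribute, and it was not tested apart from dissection.

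The fall of Rpl34 in missense exceeded that in null, by 3.29 in the test of the difference. Rpl34-ps1, a pseudogene on chromosome 6 with 26 annotated genes between it and Polr1a, lay at 6.62 to 7.19 in missense and 5.83 to 5.91 in the wild types of the missense set, but also at -3.16, -3.16 and -1.61 in wild type 1, null 1 and wild type 2 against 5.86 in null 2, so that its level varied without the missense allele. For Rpl34, null 2 lay at 7.75, against 8.32 to 8.55 in the other samples of the null set. The wild types of the missense set lay at 7.60 to 7.86 for Rpl34. Null 2 and these wild types thus had more pseudogene and less Rpl34 than the other null-set samples, without the missense allele. Reads shared with the pseudogene stay open, since the summed level of both changed by -0.967 (SE 0.183), against -3.76 for Rpl34 alone. Reads passing one for one from Rpl34, on chromosome 3, to the pseudogene are argued against as the whole cause by that fall of the sum. The gain of the pseudogene came to 33.3% of the loss of Rpl34, so such reads may account for a part. Reads counted for neither gene are not covered by this test. Sequence variants around Polr1a stay open, since 4 of 101 neighbouring genes had an unadjusted p under 0.05 in missense, at percentile 18.0 of all windows, which is below the median window of 5 by less than the spread between windows (SD 2.42). Lower Rpl34 expression from the missense allele was not tested apart from these.

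Targets of p53 were higher in both mutants, and Ccng1, the p53 target nearest to the threshold in null, stood apart in wild type 4, at 5.79 against 5.36 to 5.46 in the other wild types. The median of the list in the mean of both mutants was 0.26, and 1 of 60 splits within title numbers, the real one, reached it. The highest of the others was 0.183. This is the smallest share that 60 splits can give, and it was not adjusted for the 30 lists. Chance is argued against as the source at that share, but it is not excluded. An unequal mix of sexes is argued against, since the median stayed at 0.234 with the Y-linked level as a covariate and the list stayed called. Handling stress stays open, with a median of 0.123 for immediate early and heat shock genes (bootstrap interval -0.06 to 0.27). Microglia stay open too. With their level as a covariate the median was 0.143, above the 0.129 that would mark a fall to 50% by less than its bootstrap SE of 0.0974. With that covariate the list passed camera at the preset correlation (adjusted p = 0.00579). It missed with an estimated correlation (adjusted p = 0.251), against 0.00560 without the covariate. Only genes were resampled for the bootstrap interval and SE, so neither measures the spread between samples. A response to the Polr1a alleles may contribute, and the design cannot set it apart from a difference in microglia.

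The mean log2 level of the snoRNA host genes stood apart in wild type 2, at 3.17 against 4.10 to 4.41 in the other wild types. With 55 sets of wild-type values examined and 2 standing apart, chance alone would give about 1 in 20. The difference in change of each gene, null minus missense, had a median of 0.58 for microglia and macrophages (adjusted p = 7.34e-07; adjusted p = 0.290 with an estimated correlation), 0.40 for the choroid plexus (adjusted p = 0.00141; adjusted p = 0.290 with an estimated correlation), 0.65 for the diencephalon, hypothalamus, eye and midbrain (adjusted p = 0.00628; adjusted p = 0.819 with an estimated correlation) and 0.29 for mesenchyme, neural crest and meninges (adjusted p = 0.00617; adjusted p = 0.819 with an estimated correlation). This median of the differences was 0.23 for endothelium and pericytes (adjusted p = 0.000290; adjusted p = 0.798 with an estimated correlation) and 0.0861 for cytosolic ribosomal proteins (adjusted p = 0.0357; adjusted p = 0.819 with an estimated correlation). Microglia and choroid plexus lists also differed between the wild types, so their differences do not come from the mutants alone. Mean log2 levels of microglial genes were 1.58 and 1.66 in wild types of the null set and 2.85 and 2.71 in null. They were 1.98 to 2.33 in wild types of the missense set and 2.31 to 2.80 in missense. For choroid plexus genes, in the same order, they were 2.10 and 2.30, 2.83 and 2.91, 2.86 to 3.16, and 2.88 to 3.65.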

How the results depend on the processing

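The Y-linked covariate, the fits without wild type 4 and missense 3 together, the counts without predicted models, pseudogenes and ribosomal protein genes, and the rescaled list tests were chosen after seeing the data. The count of genes in null was within 1.5 times of 24 in 11 of 21 alternatives, that in missense in 16 of 21, that of the difference in 5 of 20, that of the mean of both in 11 of 20 and that between the wild types in 14 of 19. Where a count moved, the cause was not tested, except that fewer samples or genes were used in the fits that leave some out. Without the title-number term the counts were 59 in null and 9 for the difference, the missense change of Polr1a was 0.01 (0.00612), reversed from -0.08, and the correlation of fold changes was 0.301. Without the trend the counts were 6 in null, 0 for the difference (646 at an unadjusted p under 0.05 in limma) and 13 for the mean of both. With the samples of the title number compared alone the count in null was 0 (1101 at an unadjusted p under 0.05 in limma), and it was 4 in missense. With the Y-linked covariate the difference had 4 genes. Without wild type 4 and missense 3 together the counts were 12 in null, 8 in missense, 11 for the difference, 19 for the mean of both and 6 between the wild types, and the mesenchyme list reversed in missense, at -0.13. Without predicted models and ribosomal protein genes the counts were 0 in missense (748 at an unadjusted p under 0.05 in limma), 1 for the difference and 3 between the wild types. At or above the 25th percentile of the level 8 genes differed between the wild types, and at or above the median level the correlation was 0.387. With an estimated correlation 4 lists were called in null and 1 in missense.

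Leaving out 1 sample gave counts of 2 to 23 in null, 2 to 10 in missense, 1 to 10 for the difference, 10 to 29 for the mean of both and 7 to 21 between the wild types. The missense change of Polr1a ran from -0.22 to 0.13 and reversed without missense 1 (0.13), and the median of the mitochondrial ribosomal list in null ran from -0.17 to 0.11 and reversed without wild type 1 (0.11). Median centring gave 7 higher and 30 lower genes in the mean of both, and 1 higher and 1 lower in missense. The alternatives with Xist as a covariate (no value in the file), with pseudocounts (the values are already log2) and with edgeR or DESeq2 (no counts) were not run, nor was the fit of 1 title number alone for the difference, the mean of both and the wild types, which need both numbers. Of Polr1a and the genes that the rule named for each mutant as called or of smallest p, Polr1a alone changed sign under an alternative, and Dlx1 in null missed the threshold in 1 of 21, with the samples of its title number alone. Depth is unknown, so what it limits could not be computed.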

Other observations

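The tests of regional lists below were chosen only after the results were seen, and those of the splits were planned before.

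Within the ventral telencephalon, markers of the medial ganglionic eminence had a median log2 change of -1.93 over 8 genes in null, of which 6 were lower. Markers of the lateral ganglionic eminence had a median of -0.12 and a mean of -0.30 over 11 genes, of which 6 were lower. At an unadjusted p under 0.05 in limma, 5 medial genes were lower and 1 higher, and 5 lateral genes were lower and 2 higher. Markers of the dorsal pallium had a median of 0.10 over 15 genes in null, with a mean of -0.08. In missense the medians were -0.13 for the medial ganglionic eminence, -0.01 for the lateral ganglionic eminence and -0.16 for the dorsal pallium, of which 11 of 15 genes were lower.

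Among 60 splits of the samples within their title numbers, 1, the real one, gave as many genes in the mean of both mutants, 40 against 8 in the highest of the others. This is the smallest share that 60 splits can give, so chance is argued against as the source of that count but is not excluded. The correlation of the fold changes of null and missense was reached in absolute value by 4 of 60 splits, the real one among them. The real value was 0.104 and the highest absolute value of the others 0.113, so chance stays open for it. For the number of genes in missense, with the null samples kept as their group, the real split of the 6 samples, 1 of 10, gave 3 genes and the highest of the others 0, and 10 splits are too few for a share under 0.05. With null 1 and wild type 2 put together as a group instead, the real missense split gave 2 genes and that of wild type 3, wild type 5 and missense 3 gave 8, and with wild type 2 and null 2 together the real one gave 2 and another 4.

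Missense 3 lay at 1 end of the first principal component of all genes, at 63.0, and wild type 4 at 1 end of the second, at 65.1.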
